A study of Mus musculus with 6 samples.

How the data were processed

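Eomes, a T-box transcription factor of natural killer (NK) cells, was immunoprecipitated from the chromatin of mouse splenic NK cells. Per the labels' protocols, the cells were purified from pooled splenocytes of wild-type C57BL/6 mice aged 8 to 12 weeks and grown for 4 days in 100 ng/mL IL-15, the cytokine that keeps NK cells alive and dividing in culture. Each of 3 separate experiments gave 1 immunoprecipitated (IP) library and 1 input library of DNA that was not immunoprecipitated. Fragments of 200 to 600 bp were selected and amplified for 15 cycles, per the labels' protocols.

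The deposited files were 3 peak lists, 1 per experiment, so peaks were called per experiment and not on pooled samples. The sample descriptions pair each list with the input of the same experiment. The submitters' processing notes name the genome build mm10, Novoalign (a read aligner) and ChIPseeker (which annotates peaks), without versions or settings. The peak caller, its version and its settings are not given in the sources used here. Each peak carried a pileup, a whole number read here as the IP fragments at the peak summit, since only the column name is given. It also carried a fold enrichment, the ratio of IP to background that the authors' caller gave. The deposited −log10 p-value and −log10 q-value were the authors' own scores for each peak. The smallest −log10 q-value in the lists was 1.31, close to a q-value of 0.05. The deposited annotation gave each peak its nearest gene, the distance to a transcription start site (TSS) and a class, with promoters reaching 3000 bp from the TSS. Distances run to the nearest annotated transcript start, which can lie inside a gene. Scores and folds were used to describe, rank or filter peaks within their own list, and across lists only as rank correlations and as means ± SD that describe a region.

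Sequencing depth per library is not given in the sources used here. A proxy came from the deposited values. The background of each peak was recovered as (pileup + 1) / fold − 1, and a Poisson upper tail at that background matched the deposited −log10 p-value to within 0.000336. Each list had a lowest background that many of its peaks shared, called the floor here. The floor was 1.82 fragments in experiment 1, 1.32 in experiment 2 and 2.33 in experiment 3. The smallest pileup in a list was 8, 7 and 9 fragments, respectively, so weaker binding was not detectable at these depths.

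Rows that repeated an interval for sub-peaks were collapsed to 1 row per interval, keeping the sub-peak with the highest −log10 q-value. Peak names are numbered in sequence, and 20, 23 and 25 numbers of the 3 sequences have no row in the lists used here. The length column exceeded the printed interval by 1 bp in 100% of rows, so starts may be shifted by 1 bp. Coordinates are printed as the lists give them, on mm10. Intervals sharing at least 1 bp were merged into regions, and a region with a peak from at least 2 of the 3 experiments was called reproducible. The merging function was checked against bedtools 2.31.1, and both gave 20126 reproducible regions. The chance level came from 100 shuffles of each list within its chromosomes, with widths kept, over 21 main chromosomes. The one-sided permutation p cannot go below 0.0099. Overlaps between lists were counted in both directions against the same shuffles. Spearman's rho compared −log10 q-values across regions found in all 3 lists. Regions are not independent replicates, so no p was computed. Each region took the annotation of its highest-ranked peak, and shares have 95% Wilson intervals that cover counting error only.

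Genes were matched by symbol, or by a unique synonym on the same chromosome, to 21887 protein-coding RefSeq genes of GRCm38.p6, the assembly behind mm10. Of the intervals, 74.7%, 77.4% and 76.8% in the 3 lists matched such a gene. A gene counted as covered when a reproducible region was assigned to it. A peak over a gene can be assigned to a neighbour with a nearer TSS, and this held for a reproducible region at 3 of the 19 named genes with no assigned peak, while 15 had no peak over the gene at all. The 13 gene lists were fixed before the data were examined. They covered NK receptors, cytotoxic machinery, cytokines and chemokines, cytokine receptors and signalling, NK and ILC1 transcription factors, migration and adhesion, cell cycle and survival, and ribosomal protein genes. The other lists held T cell genes, B cell genes, myeloid genes, mesoderm and endoderm genes, and liver and neuronal genes. Of 305 members, 304 were in the gene table, with Zfp683 the exception. Coverage of each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 13 lists and a threshold of 0.05. Genes are not replicates of the experiment, so these tests describe the merged lists. Tested on simulated coverage of 21887 genes at 45%, the cytotoxic list (20 members) planted at 90% was called in 44 of 50 runs. With nothing planted, any list was called in 1 of 50 runs. Genes were drawn independently there, so these rates need not hold for real lists, whose members can be neighbours or differ in locus span. In simulated peak lists with 5000 sites placed in all 3 lists, 5000 regions in all 3 were counted. The placed peaks overlapped by design, so this checked the counting only.

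The genes named here followed a rule fixed before the data were examined. It always named 14 genes (Eomes, Tbx21, Ifng, Prf1, Gzmb, Ncr1, Klrb1c, Klrg1, Il2rb, S1pr5, Itga1, Itga2, Zeb2 and Prdm1). For each list it added up to 4 members with a peak in all 3 experiments, by the mean percentile of the best peak within each list, and up to 2 members with no peak, in alphabetical order. It also took the 10 regions whose lowest percentile over the 3 lists was highest. Fold values are given as the mean ± SD over the experiments with a peak in the gene's leading region, the one found in most lists and ranked highest. A few items that the rule selected are not reported here.

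Alternatives fixed before the data were examined covered the number of lists required, the overlap required, score thresholds, list length, the promoter window, assignment distance, random lists matched on the span of the locus, and leaving out each experiment. A share of regions with T-box motifs had been planned but was not run, because no genome sequence was used here. The share of promoter regions expected by chance was not computed, because the gene table used here has no strands. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.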

Results

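Eomes binding was mapped by chromatin immunoprecipitation and sequencing in splenic NK cells expanded with IL-15 for 4 days, to ask where in the genome of these cells the factor sits. The data comprised 3 IP libraries and 3 input libraries from 3 separate experiments, each pair giving 1 peak list. After collapsing sub-peaks, the lists held 37456, 33841 and 46329 intervals in experiments 1, 2 and 3. Their median lengths were 200, 201 and 240 bp. The median pileup at the summit was 12, 11 and 14 fragments, and the median fold enrichment over background was 4.10, 4.67 and 4.08. Fold values are those of the authors' lists, given as the mean ± SD over experiments.

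The regions that ranked highest over the 3 experiments lay both at promoters and at distal sites. The leading region on chromosome 9 (107333344 to 107334809) was a promoter region assigned to Hemk1, with a fold of 29.8 ± 5.10 (SD, n = 3). Promoter regions of Ccng2, which encodes a cyclin, Tmem134, Bhlhe40, a helix-loop-helix repressor, and Smc5 had folds of 28.5 ± 2.43, 32.9 ± 7.16, 24.6 ± 5.41 and 24.3 ± 5.36 (SD, n = 3 each). A region on chromosome 11 (77111149 to 77111562) within 3000 bp of Gm12344 had 33.7 ± 5.03. Away from promoters, the top 10 included a site assigned to Irf8 in an intron of another gene (27.4 ± 8.41), an intergenic site near Gm23387 (29.8 ± 2.98) and an intergenic site upstream of the chemokine gene Ccl5 (21.4 ± 1.38).

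Merging the 3 lists gave 84399 regions. Of these, 10328 (12.2%) were found in all 3 experiments, 9798 (11.6%) in 2 and 64273 (76.2%) in 1. The 20126 reproducible regions included 20070 on the main chromosomes, against 1012 ± 28.8 (SD over 100 shuffles) by chance, a 19.8-fold excess (one-sided permutation p = 0.0099, the smallest the shuffles can give). For regions in all 3 lists, 10289 on the main chromosomes stood against 5.50 by chance. Against peaks moved locally by 10000 to 50000 bp, a setting chosen after the data were seen, the excess was smaller, at 6.19-fold for at least 2 lists and 103-fold for all 3, where the mean chance level was 99.7 regions. Between pairs of experiments, the share of peaks overlapped by the other list ran from 32.0% (experiment 1 by experiment 2) to 45.9% (experiment 2 by experiment 3), and the highest mean was 1.08% over shuffles and 3.78% over peaks moved locally. Scores of regions in all 3 lists were correlated between experiments across regions, with Spearman's rho of 0.56 for experiments 1 and 2, 0.64 for 1 and 3, and 0.61 for 2 and 3. Leaving out experiment 3, which had the longest list, left 11650 regions shared by the other pair.

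Sharing was highest among the top-scoring peaks. In the highest score decile, 98.5%, 92.4% and 98.3% of peaks of experiments 1, 2 and 3 overlapped a peak of another experiment. In the lowest decile, 28.6%, 30.1% and 19.6% did so, against shuffled levels between 1.49% and 1.66%. Shuffled levels by decile are means over 20 shuffles of the other lists. Below the eighth decile the share did not rise steadily with score. It was 20.1% in decile 2 and 27.6% in decile 5 of experiment 1, and 17.3% in decile 3 of experiment 3. The comparisons that follow use reproducible regions.

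**Figure D1:**
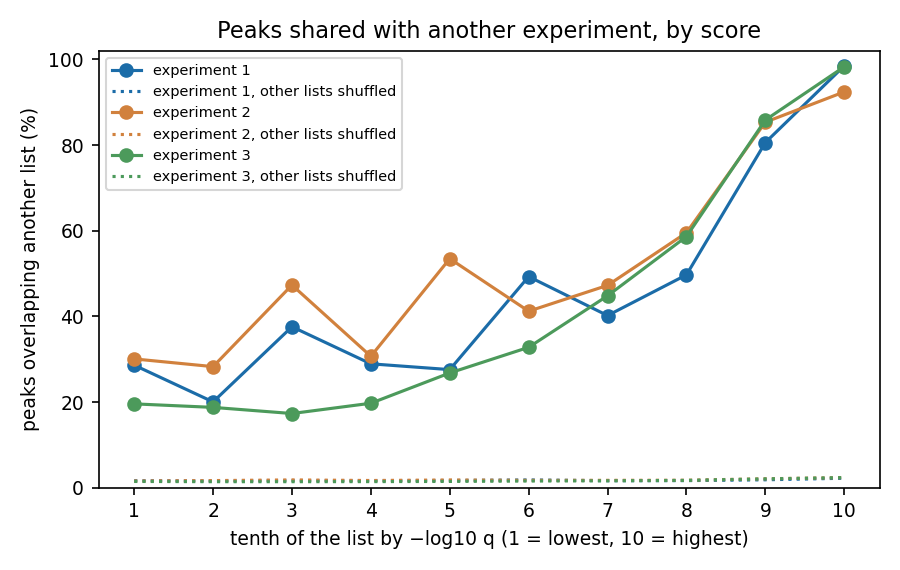
The horizontal axis gives the decile of each peak list by −log10 q-value (tied scores stay together) and the vertical axis the percentage of its peaks that overlap a peak of another experiment. Solid lines with points are the 3 experiments and dotted lines the mean level over 20 shuffles of the other lists. Sharing reaches 98.5%, 92.4% and 98.3% in the highest decile of experiments 1, 2 and 3, while the shuffled level stays at or below 2.39%.

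Eomes peaks shared between experiments lay at promoters more often than peaks of 1 experiment. Promoter regions made up 59.1% of reproducible regions (95% Wilson interval 58.4 to 59.8%), introns 18.0% and distal intergenic sequence 18.1%. The promoter share was 30.0% for regions in 1 list (29.7 to 30.4%), 54.1% for regions in 2 lists (53.1 to 55.1%) and 63.8% for regions in 3 lists (62.9 to 64.7%). Counted per experiment, promoters held 61.3 ± 1.79% of peaks shared with another experiment and 29.8 ± 3.52% of the others (SD, n = 3), and the share was higher for shared peaks in 3 of 3 experiments. The paired difference was 31.5 ± 3.08 percentage points (SD, n = 3), with a two-sided exact permutation p of 0.25, the smallest that 3 pairs allow. The 3 differences are not independent, since the 10328 regions in all 3 lists enter the shared peaks of each experiment. The SD and p therefore rest in part on the same regions. Among the 2000 strongest regions in all 3 lists, a set chosen after the data were seen, promoters made up 50.1%.

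**Figure D2:**
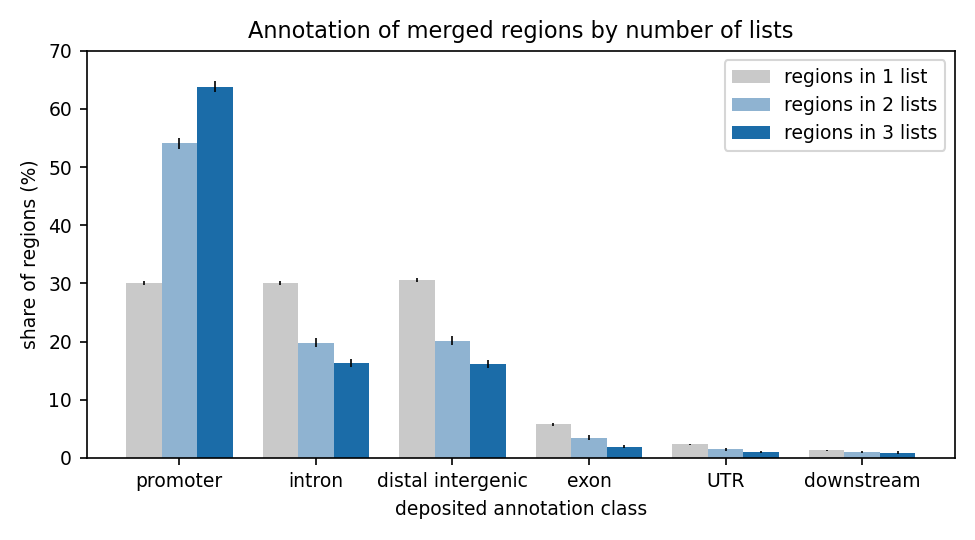
Bars give the percentage of merged regions in each deposited annotation class (horizontal axis) for regions found in 1, 2 or 3 lists, with 95% Wilson intervals as error bars. The promoter share is 30.0%, 54.1% and 63.8% for regions in 1, 2 and 3 lists, while the intron and distal intergenic shares are lower in 3 lists than in 1.

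Reproducible regions were assigned to 9803 of 21887 protein-coding genes (44.8%). Of the 13 gene lists, 7 were covered more often than other genes (Fisher's exact test, adjusted p at or below 0.0042). They were the transcription factors, the cytotoxic machinery, cell cycle and survival genes, cytokine receptors and signalling, cytokines and chemokines, migration and adhesion, and ribosomal protein genes. The same 7 lists were covered more often in 3 of 3 experiments taken alone, and 6 of them passed the test in each. Cytokines and chemokines passed in 2 of 3 and not in experiment 2, where the excess was 17.5 percentage points.

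All 33 transcription factors of the NK and ILC1 list in the gene table had a reproducible region (100%, Wilson interval 89.6 to 100%, against 44.7% of other genes, exact adjusted p = 3.9e-11). The list carried 177 reproducible regions in total. The leading regions of Irf8 (fold 27.4 ± 8.41), Bcl11b (23.2 ± 9.42), Tcf7 (20.9 ± 2.87) and Tox2 (20.1 ± 1.92, SD, n = 3 each) lay outside promoters. Tcf7 encodes TCF-1, a factor of early T and NK cell development, and its region lay on chromosome 11 (52299509 to 52300222) at -16495 bp from the TSS. Eomes itself had 8 reproducible regions, led by its promoter (chromosome 9, 118478420 to 118479251, fold 5.81 ± 0.48). Prdm1, which encodes the repressor Blimp-1, also had 8, led by an intergenic site with 7.91 ± 2.98. Zeb2 had 2, with a promoter fold of 4.14 ± 1.12. Tbx21, which encodes the related T-box factor T-bet, had 2 promoter regions shared by experiments 1 and 3 and no peak in experiment 2. Its leading fold was 4.55 ± 2.14 (SD, n = 2), and no region remained for Tbx21 when experiment 1 or experiment 3 was left out.

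Cytotoxic genes were covered at 19 of 20 (95%, interval 76.4 to 99.1%, exact adjusted p = 1.2e-05), with Stxbp2 the exception. Prf1, which encodes the pore-forming protein perforin, had a peak over its promoter in every experiment (chromosome 10, 61297456 to 61297882) with a fold of 12.8 ± 0.54 (SD, n = 3). The granzyme gene Gzmb had 4 regions found in all 3 lists, the leading one in the promoter class (6.38 ± 2.11). Gzma had 4 reproducible regions, led by a site 9945 bp downstream of the TSS, beyond the end of the gene, at 14.0 ± 4.94. Tnfsf10, which encodes the death ligand TRAIL, had the highest-ranked site of the list, an intronic region 5576 bp downstream of the TSS on chromosome 3 (27322486 to 27323245, fold 19.99 ± 3.86). Srgn, which encodes the granule proteoglycan serglycin, had an upstream site at 12.0 ± 2.37.

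Cytokine and chemokine genes were covered at 12 of 14 (85.7%, interval 60.1 to 96.0%, exact adjusted p = 0.0042). The 4 highest-ranked members had their leading sites outside promoters. The site upstream of Ccl5 (chromosome 11, 83534989 to 83535473) lay at -4471 bp from the TSS. Il10 had a site 5861 bp downstream of its TSS (fold 19.7 ± 0.98), and Xcl1 one at -30533 bp (19.5 ± 3.49). Ifng, which encodes interferon gamma, had 5 reproducible regions and none of these in its promoter. Near the start of the gene, experiment 3 alone had a peak (118441101 to 118441275, fold 2.82). Reproducible regions of Ifng were thus all outside the promoter. The leading region lay 29352 bp downstream of the TSS on chromosome 10 (118470389 to 118470919) with 10.3 ± 2.96. No peak was assigned to Flt3l, although peaks over the gene, with 1 reproducible region among them, were assigned to Gm45713 or Rpl13a. Counting promoter regions alone, 8 of 14 members were covered against 38.4% of other genes, and the list no longer passed the test.

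**Figure D3:**
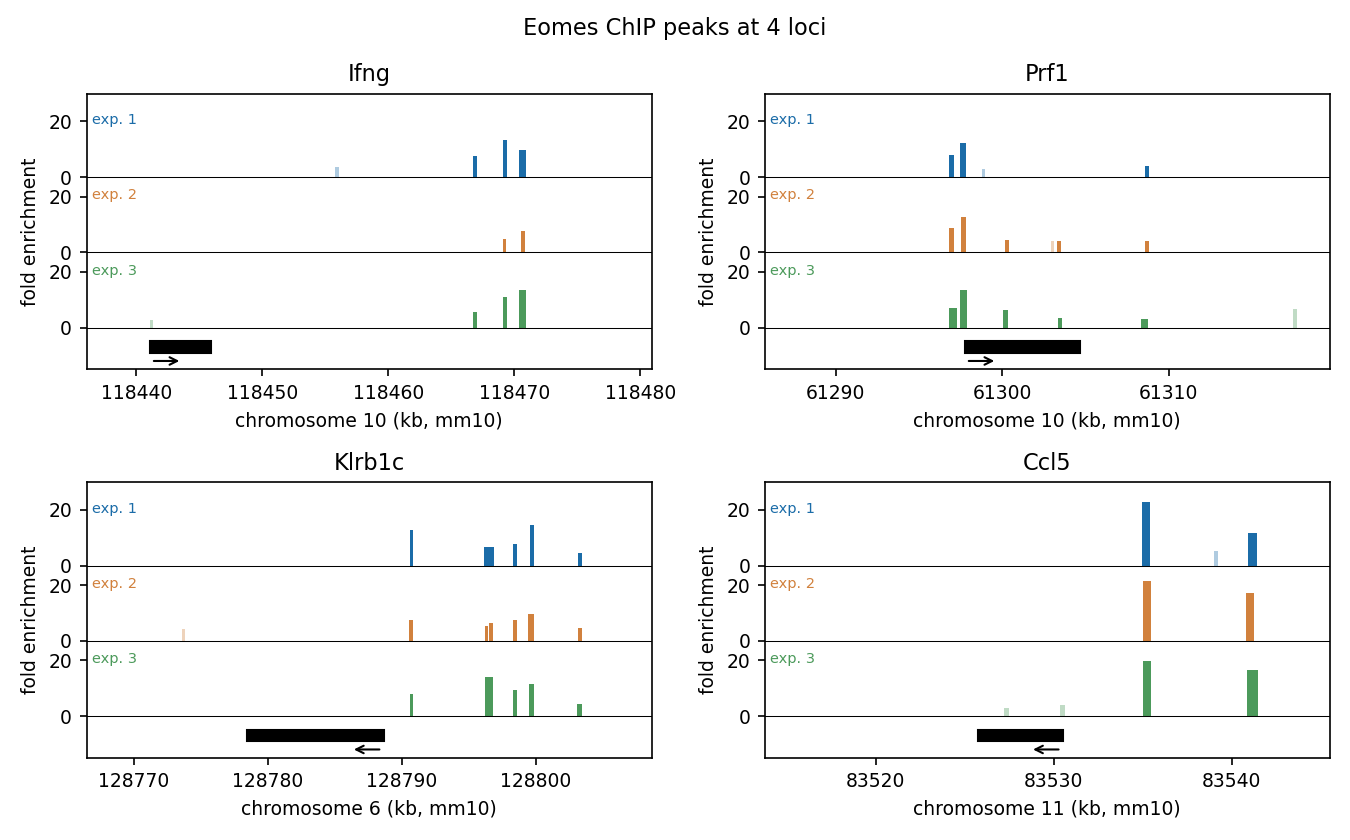
Each panel maps 1 locus on mm10 (horizontal axis in kb), with the gene as a black box and an arrow at its TSS pointing in the direction of transcription. Bars are deposited peaks, as wide as the peak or a small minimum, with height giving fold enrichment, in separate tracks for experiments 1, 2 and 3, and pale bars are peaks of regions found in 1 list. Prf1 carries its highest peak at the promoter in each experiment (folds 12.3, 12.7 and 13.4), while the highest peaks shared by all experiments at Ifng, Klrb1c and Ccl5 lie outside the gene.

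Genes of cytokine reception were covered at 25 of 29 (86.2%, interval 69.4 to 94.5%, exact adjusted p = 1.8e-05). Il2rb, the receptor chain shared by IL-2 and IL-15, had a promoter region (chromosome 15, 78494980 to 78495536) with a fold of 13.4 ± 0.59. The IL-12 receptor gene Il12rb2 had 15.0 ± 2.20 at its promoter. Smad3, a transducer of TGF-beta signals, had 18 reproducible regions, led by one at 14.8 ± 5.11, and the signalling inhibitor gene Socs1 had 10, led by one at 14.0 ± 2.02. No peak was assigned to the receptor genes Il2rg and Il7r in any experiment. Il2rg lies on the X chromosome, where only 10.97% of genes had a reproducible region, against 46.9% on the autosomes.

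Among migration and adhesion genes, 20 of 24 were covered (83.3%, interval 64.1 to 93.3%, exact adjusted p = 0.00029). The integrin genes Itgb2 and Itgb7 had intronic sites with folds of 14.5 ± 0.66 and 12.97 ± 5.21. Cxcr3, a chemokine receptor gene on the X chromosome, had 15.5 ± 3.28, and the selectin ligand gene Selplg had 9.17 ± 1.74 at its promoter. S1pr5, a receptor used by NK cells to leave lymphoid tissue, had 9.63 ± 1.32 at -1596 bp. Of the integrins used to tell NK cells from ILC1, Itga1 had a promoter region at 7.35 ± 0.79 and Itga2 one at 4.61 ± 0.43 (SD, n = 3 each). Ccr2 and Cd69 had no assigned peak.

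Genes of NK receptors were covered at 18 of 35 (51.4%, interval 35.6 to 67.0%), against 44.8% of other genes. The difference did not pass the test (exact adjusted p = 0.54). Taken alone, experiments 1, 2 and 3 placed the list 0.16, -2.55 and -5.81 percentage points from other genes, and it passed in none. The list was split. Klrg1 (fold 13.6 ± 4.80 at a site 23530 bp downstream of the TSS), Cd244a (12.3 ± 0.66), Klrb1c, which encodes NK1.1 (11.8 ± 2.58), and the adaptor gene Tyrobp (10.7 ± 1.41) ranked highest. Klrb1c had 6 regions found in all 3 lists, and its leading region lay on chromosome 6 (128799449 to 128799899) at -10316 bp. Ncr1, which encodes NKp46, had a promoter region with 8.48 ± 2.37. None of the 9 Klra genes, which encode Ly49 receptors, had a reproducible region, and 2 of them had a peak in 1 experiment, whereas 18 of the other 26 members had a reproducible region. This split was made after the values were seen. Whether reads could be placed uniquely at the Klra genes was not examined, so a missing peak there does not show absence of binding. Cd226 and Cd96 had no assigned peak. Within the 2000 strongest regions, a set chosen after the data were seen, 7 of 35 NK receptor genes were covered against 6.30% of other genes, and the list passed the test.

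Cell cycle and survival genes were covered at 27 of 30 (90%, interval 74.4 to 96.5%, exact adjusted p = 1.9e-06), and 26 of the 30 had a promoter region. Bcl2l11, which encodes the death-promoting protein Bim, had a leading intronic site at 11.1 ± 1.05. Promoter regions led at Mcm7 (10.4 ± 3.06), the cyclin gene Ccnd3 (10.1 ± 2.84) and the cell cycle inhibitor gene Cdkn1a (9.57 ± 3.34). Ribosomal protein genes, included as a list of active promoters unrelated to NK cell identity, were covered at 24 of 30 (80.0%, interval 62.7 to 90.5%, exact adjusted p = 0.00029), with promoter regions at 23 of 30. Rpl37 and Rpl10a had promoter folds of 11.5 ± 0.15 and 7.75 ± 2.58. The leading sites of Rplp1 (11.5 ± 4.46, 248007 bp from the TSS) and Rps14 (10.2 ± 4.19) were distant sites assigned by proximity. Rpl23 and Rpl32 had no assigned peak, though peaks over both genes were assigned to other genes within them or nearby. Outside promoters, coverage was 2 of 30 for ribosomal protein genes and 7 of 30 for cell cycle genes, against 15.2% and 15.1% of other genes, and neither list passed the test. In that setting, chosen after the data were seen, 22 of 33 transcription factors and 9 of 20 cytotoxic genes were covered, and both lists passed, but so did T cell genes (7 of 19) and myeloid genes (7 of 17).

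**Figure D4:**
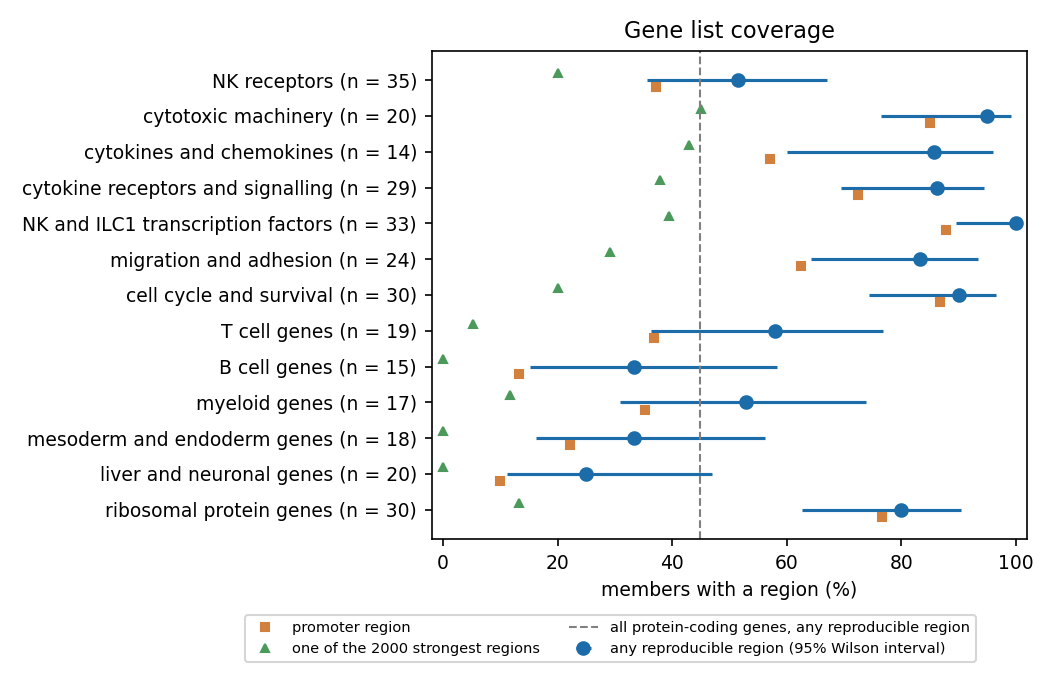
Rows are the 13 gene lists with the number of members in parentheses, and the horizontal axis gives the percentage of members with a region. Circles with 95% Wilson intervals count any reproducible region, squares promoter regions and triangles the 2000 strongest regions, and the dashed line marks the 44.8% of all protein-coding genes with a reproducible region. The circles of 7 lists lie between 80.0% and 100%, while those of NK receptors and the lists of other lineages lie between 25.0% and 57.9%.

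With any reproducible region counted, no list of another blood lineage passed the test, but the lists are short and their intervals wide. Outside promoters, T cell and myeloid genes were covered more often (36.8% and 41.2%, against 15.1% of other genes for each). T cell genes were covered at 11 of 19 (57.9%, interval 36.3 to 76.9%, exact adjusted p = 0.37). B cell genes were covered at 5 of 15 (33.3%, interval 15.2 to 58.3%, exact adjusted p = 0.52). For myeloid genes it was 9 of 17 (52.9%, interval 31.0 to 73.8%, exact adjusted p = 0.63). Taken alone, 3 of 3 experiments had T cell and myeloid genes above other genes, and T cell genes passed the test in experiment 1 only. Several covered T cell genes are also used by NK cells, such as Lck (12.1 ± 2.56), Cd247 (8.32 ± 1.95) and Zap70 (6.53 ± 0.83), and Cd3d had a site at 9.47 ± 3.44. Cd3g and Cd8b1 had no peak. Among B cell genes, Bank1 (5.19 ± 1.63), Cd22 (3.61 ± 0.43) and Pax5 (4.93 ± 0.95, n = 2) had reproducible regions, Ebf1 had peaks in every experiment that did not overlap, and no peak was assigned to Cr2 or Fcer2a (a region over Fcer2a was assigned to Trappc5). Pax5 lost its region when experiment 1 or experiment 2 was left out. Of the myeloid genes, Spi1 had 12.9 ± 4.44, Cd68 12.1 ± 2.40, Cebpb 10.2 ± 4.56 and Itgax 6.5 ± 1.40, while S100a8 and Clec4d had no peak.

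Mesoderm and endoderm genes, a programme tied to Eomes in the early embryo, were covered at 6 of 18 (33.3%, exact adjusted p = 0.46). Sox17 had a promoter region at 3.86 ± 0.70. Tbx6 (5.41 ± 0.11) and Nodal (5.15 ± 0.26) had regions in experiments 1 and 3 only (n = 2 each), which were lost when either was left out, and Cer1 and Tdgf1 had no peak. Without experiment 1, the mesoderm and endoderm list lay 31.9 percentage points below other genes, a difference that passed the test. With each experiment taken alone, the list lay above other genes in 3 of 3, by 17.7 to 18.3 points, and passed the test in none. Liver and neuronal genes were covered at 5 of 20 (25.0%, exact adjusted p = 0.18). Neurog2 had a site at 7.50 ± 2.91, Slc17a7 (5.73 ± 1.29) and Rbfox3 (4.47 ± 0.38) had regions in 2 experiments, Syt1 had peaks that did not overlap, and Alb and Apoa1 had none. Slc17a7 lost its region without experiment 1, and Rbfox3 without experiment 2 or experiment 3. Promoter regions alone covered 2 of 20 liver and neuronal genes against 38.5% of other genes, and that difference passed the test.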

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

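The peaks moved locally, the removal of peaks with a high background, the non-promoter regions, the 2000 strongest regions and the 10000 random lists were chosen after seeing the data. No paired analysis was possible because each deposited list already sets the IP against its own input and holds no separate input values. This limit concerns IP against input, paired by experiment. The pileup was read as an IP value, but the background was recovered from pileup and fold, and many peaks of a list shared its floor. The paired promoter difference in the results compared shared with other peaks of the same experiment. The planned T-box motif alternatives were not run, for want of a genome sequence here. Of the alternative values of the comparisons, 183 kept their direction and side of the threshold or moved little, 10 moved further, 10 changed sign, 7 newly passed the threshold and 3 no longer did. In number, 7 lists were above the other genes under each setting except promoter regions only, which left 6. The 7 lists called outside promoters and in the 2000 strongest regions were not the same as in the report. Of 59 named genes with a reproducible region, 7 had none when all 3 lists were required, and 2 to 6 when 1 experiment was left out.

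The 20126 reproducible regions became 10328 when all 3 lists were required, 12223 for the top 50% of each list by score and 11650 to 14602 with 1 experiment left out, by construction, since fewer peaks or lists enter. With fold in place of q, rho was 0.49, 0.54 and 0.53 for experiments 1 and 2, 1 and 3, and 2 and 3. The promoter share of 59.1% was 50.9% within 1000 bp of the TSS, 64.3% within 5000 bp, 63.8% in all 3 lists and 59.5 to 63.3% with 1 experiment left out.

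List values are percentage points above other genes, and for those that changed the cause was not tested. Promoter regions only gave NK receptors -1.31, T cell genes -1.61 and myeloid genes -3.16 (a change of sign, none past the threshold), cytokines and chemokines 18.7 (no longer past it), and liver and neuronal genes -28.5 (now past it). Non-promoter regions gave B cell genes 4.84, mesoderm and endoderm genes 7.07, liver and neuronal genes 4.84 and ribosomal protein genes -8.50 (a change of sign), cell cycle genes 8.18 (no longer past the threshold), and T cell genes 21.7 and myeloid genes 26.0 (now past it). In the 2000 strongest regions, NK receptors had 13.7 (now past it), ribosomal protein genes 7.02 (no longer past it) and T cell genes -1.06 (a change of sign). Within 10000 bp of the TSS, myeloid genes had -5.85 and liver and neuronal genes -26.2, the latter now past the threshold. In all 3 lists, mesoderm and endoderm genes had -24.3, now past it, and with 1 experiment left out they ranged from -31.9 to -8.27, past it without experiment 1. With 1 experiment left out, myeloid genes ranged from -0.75 to 10.2, B cell genes from -24.1 to -9.38, NK receptors from 8.30 to 12.6 and T cell genes from 15.2 to 21.9, none past the threshold. Without peaks of high background, myeloid genes had 2.52. Library depth is unknown here, so its effect on weak peaks was not tested.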

Other observations

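The test of the genes with the most regions was chosen only after that pattern was seen, as were the settings named above. The number of reproducible regions per gene had a long upper end. Id2, which encodes a transcription regulator that NK cells need, had 29, the most of any protein-coding gene, followed by Mroh2a with 26, Gse1 with 25, and Nfatc1 and Septin9 with 20 each. Smad3 had 18, and genes with 17 included Runx1, Ctdp1, Prex1, Sik1 and Zfp36l2. Irf8 and Lef1 had 14 each. These genes were chosen by their count after the values were seen. One technical explanation, a high local background as over collapsed repeats, needs a median background above 2 times the floor of the list for at least 10 of the 20 genes. It held for 1 of the 20, Mroh2a, at 4.50 times the floor and with a median fold of 2.97. For Id2 the background was 1.40 times the floor and the median fold 5.39. The bound for the 20 genes as a set was therefore not met, and apart from Mroh2a the medians lay between 1.13 and 1.44 times the floor. A median does not show single peaks of high background, so the explanation was not excluded gene by gene. The size of the gene neighbourhoods was not tested as another explanation.

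The X chromosome carried few peaks. Of its 966 protein-coding genes, 106 (10.97%) had a reproducible region, against 46.9% on the autosomes, where single chromosomes ranged from 37.1% to 54.1%. Experiments 1, 2 and 3 listed 139, 202 and 254 peaks on X, against 1741, 1569 and 2150 for autosomal peaks scaled by gene number. On the Y chromosome, 13 of 14 reproducible regions lay past 90 Mb at its distal end, and the other was at Uty, with folds of 4.31 in experiment 2 and 7.51 in experiment 3 and no peak in experiment 1. A candidate explanation for X is 1 X copy per cell, as in male mice, since the labels give no sex. Halving the IP and background of every autosomal peak, with the background not below the floor, predicted 382, 375 and 637 peaks on X, and the observed number was 0.364, 0.539 and 0.399 of that (mean 0.434), which argues against copy number as the whole cause if X genes hold as many sites as autosomal genes. The other explanation, fewer sites of unchanged strength, needs the X to autosome ratio to be alike for strong and for all peaks. At a −log10 p-value of 10 or more the ratio was 1.64, 1.43 and 1.38 times that of all peaks (mean 1.49), on either side of the bound of 1.5 set for the test, so it stays open. A mixture of both, or a treatment of X reads before the lists were made, was not tested, and no biological explanation was tested because the design has 1 cell type.

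Promoter regions at ribosomal protein and cell cycle genes may reflect signal at any active promoter, with no selection of NK cell genes. In that case their promoter regions would rank no lower than those of the 6 lists of NK cell genes. The lowest percentile of a region was taken over the experiments with a peak in it, and each gene counted by its best promoter region. Genes without a reproducible promoter region were left out. The median was 58.8 for 49 genes of the former and 69.9 for 103 genes of the latter. The difference was -11.2 points (two-sided permutation p = 0.23 over 100000 permutations). The difference exceeded the bound of 5 points but not the spread between genes, so the explanation cannot be told apart from selective binding at promoters. The medians of the single lists overlap only through cytokines and chemokines (8 genes), and the other NK cell lists lay above both lists of the former group. As the permutation test was not passed, both stay open. By list, the medians were 49.1 for ribosomal protein genes (23 genes) and 65.0 for cell cycle genes (26 genes). For the NK cell lists they were 47.4 (cytokines and chemokines, 8 genes), 67.8 (cytokine receptors, 21 genes) and 69.2 (transcription factors, 29 genes). The others were 69.9 (cytotoxic machinery, 17 genes), 77.6 (migration and adhesion, 15 genes) and 82.3 (NK receptors, 13 genes). No open chromatin or expression data were used here, and no biological explanation was tested.

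Experiment 2 had more strong peaks of its own than the others. In its highest score decile, 253 of 3330 peaks (7.60%) overlapped no peak of another experiment, against 57 of 3740 (1.52%) in experiment 1 and 80 of 4604 (1.74%) in experiment 3. Of the 253, 18.2% were promoter peaks, against 56.6% of the shared peaks of that decile. The strongest lay on chromosome 9 (62608463 to 62608801), -69025 bp from the Itga11 TSS, with a fold of 36.6 and a pileup of 84. Over the 3 lists, 1320 intervals (1.12%) had a background above 3 times the floor, and 144 of these lay on a single unplaced contig.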
